A study of Homo sapiens with 12 samples.

How the data were processed

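Gene expression was measured in 22Rv1 and LNCaP, both established human prostate cancer cell lines, on 12 two-colour Agilent 4x44K arrays. Each array held cells transfected with a small interfering RNA (siRNA) against SMARCB1, SMARCA4 or SMARCA2, labelled with Cy3, and cells of the same line transfected with a non-targeting siRNA, labelled with Cy5, per the labels. The dyes were not swapped on any array. Cells received 20 uM siRNA 12 h and 36 h after plating, per the labels. Each of the 6 groups (3 targets in 2 lines) had 2 arrays, 1 for each of 2 siRNA sequences. The same 2 sequences were used in both lines, and the labels name 1 control replicate without saying whether 1 RNA served all arrays of a line. The arrays lay on 3 slides of 4. Slide 1 held the 22Rv1 arrays of SMARCB1 and SMARCA4, slide 2 those of SMARCA2 in 22Rv1 and SMARCB1 in LNCaP, and slide 3 the LNCaP arrays of SMARCA4 and SMARCA2.

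The deposited scanner files give the mean intensity and the local background of each spot in both channels as scanned, per the file headers. They also give processed intensity values, which Agilent Feature Extraction had background-subtracted, detrended and dye-normalised, per the file headers. Their log10 ratio is red over green, non-targeting over SWI/SNF siRNA, per the file headers. The headers name Feature Extraction 9.5.1.1 and the submitters' processing notes name 8.5.1.1. The deposited value table holds log2 ratios of Cy5 over Cy3. On all 12 arrays these equalled the scanner ratio on the log2 scale to within 5e-12 for 43529 features.

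Here every ratio was turned to siRNA over non-targeting, so that a negative log2 ratio means less transcript after the siRNA. Mean intensities were corrected with the normexp model of limma (version 3.58.1, R 4.3.3) with an offset of 50 and normalised by loess within each array. Control spots and spots marked as outliers by the scanner software were left out, and spots of a probe were averaged. Probes well above background in either channel on at least 2 of the 12 arrays were kept, which left 29833 probes. The probe with the highest mean intensity stood for its gene, which gave 22091 gene features. Of these, 14565 matched a gene symbol in the reference list (assembly GRCh38.p14, used for names alone) and 7526 did not. Probe positions are those of the files, on hg18.

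One limma model with a mean for each group was fitted to all 12 arrays, with 6 residual and 5.50 prior degrees of freedom. From it came the mean of both lines for each target, each target in each line, the differences between targets and the differences between lines. Tests were two-sided, with moderated statistics and Benjamini-Hochberg adjustment at 0.05. Against the non-targeting channel the ratio was tested against 0, so the p-values leave out the spread of the control, and a gene-specific dye effect cannot be separated from a change there. The dye effect cancels in a difference between targets within a line, and so does the control if it was 1 RNA. The 4 arrays of a target over both lines hold 2 siRNA sequences, so they are not 4 independent sequences. The labels call the arrays of a group biological replicates but do not say that they came from separate cultures, so the p-values measure the spread between these samples, which may be technical and includes the difference between the siRNA sequences.

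Named genes followed a rule fixed before the data were examined. For each mean of both lines these were the 10 largest rises and 10 largest falls past the threshold, of 1 sign on all 4 arrays, with both channels well above background on all 4. For the other comparisons the number was 5 in each direction, with arrays of the compared groups not overlapping. Up to 3 genes in each direction with a channel near background were given as bounds, up to 4 members of a gene list could be named, and features without a symbol were counted but not ranked. A set of 35 gene lists was fixed beforehand and tested with camera at a preset correlation of 0.01, adjusted over lists, then again with an estimated correlation and with fry.

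Both steps were tested on simulated data. For the mean of SMARCB1 knockdown over 22091 features, 98% of genes changed by 0.5 log2 and 100% of those changed by 1 log2 were called, with 12 other genes. For the difference of SMARCB1 and SMARCA4 the shares were 87% and 100%, with 9 others, and for SMARCB1 in 22Rv1 alone 90% and 100%, with 12 others. The changes were planted alike in both lines, so the line difference held none, and 0 genes were called there. How often a true line difference would be found was not tested. A planted shift of -0.3 log2 in a list was found as -0.29, with 0 of the other lists called. These simulations held no dye effect and no deviation of a shared control. They therefore do not show how many false calls either would give against the non-targeting channel. In a separate simulation of unchanged groups with a shared control, 193 higher and 205 lower features were called for both SMARCB1 and SMARCA4 means. The simulated genes were independent of each other, so list calls that arise from correlation between genes could not show. In the data that correlation was estimated at 0.604 for the G1/S and 0.814 for the G2/M list.

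Alternatives covered background correction, offset, normalisation, the filter on dim probes, the choice of probe, moderation, array weights, the size of change, the arrays in the fit, blocks by slide and siRNA number, a block by siRNA sequence and 1 value per siRNA sequence (both chosen after the data were seen), and each array left out in turn. Spots well above background made up 49.9% to 62.4% of 43376 in the siRNA channel and 62% to 69.1% in the non-targeting channel, and the number of arrays limits the precision. Sites matching the siRNA sequences in other transcripts were not searched, since that needs transcript sequences.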

Results

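The series asked how the transcripts of prostate cancer cells differ when a subunit of SWI/SNF, an ATP-dependent chromatin remodelling complex, is depleted. SMARCB1 is a core subunit, and SMARCA4 (BRG1) and SMARCA2 (BRM) are its alternative ATPases. The 12 two-colour arrays covered 3 targets in 22Rv1 and LNCaP, 2 arrays in each of 6 groups, and each array compared 1 targeting siRNA with the non-targeting siRNA of its line. Of 43376 spots, between 49.9% and 62.4% in the siRNA channel and between 62% and 69.1% in the non-targeting channel were well above background. The LNCaP array of SMARCA4 siRNA 1 had the lowest share in the siRNA channel, 423 spots marked as outliers against 124 to 255 on the other arrays, and a standard deviation of log2 ratios of 0.316 against 0.183 to 0.251. Values below are log2 ratios of siRNA over non-targeting with their standard error unless stated otherwise.

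The targeted genes were examined first. SMARCB1 (probe A_23_P68824, hg18 chromosome 22, 22475602 to 22489008) was lower on all 4 of its arrays, at -1.25 and -0.97 in 22Rv1 and -0.79 and -0.74 in LNCaP. Its siRNA channel was not well above background there, so these are bounds, at least 2.16-fold lower in 22Rv1 (limma, adjusted p = 0.000341) and at least 1.7-fold lower in LNCaP (adjusted p = 0.00194). SMARCA2 (probe A_23_P60354, chromosome 9, 2182841 to 2182900) fell to -1.85 and -2.02 in 22Rv1 and -0.97 and -0.53 in LNCaP, with adjusted p = 1.5e-05 and 0.00425. Without the LNCaP array of siRNA 1 the LNCaP value of SMARCA2 was -0.53 (adjusted p = 0.18). SMARCA4 was measured by 3 probes. The brightest (A_23_P39034, chromosome 19, 11033673 to 11033732) read -2.22 and -2.16 in 22Rv1 (adjusted p = 0.000561, or 0.076 without siRNA 1) but -0.07 and -0.39 in LNCaP (adjusted p = 0.408). The next one (A_23_P39040, 11030037 to 11030520) read -1.69 and -1.90 in 22Rv1 and -1.04 and -1.24 in LNCaP (adjusted p = 0.00049 in LNCaP). The third probe (A_24_P212851) read -0.24 ± 0.23 in 22Rv1 and -0.49 ± 0.08 in LNCaP (SD, n = 2 each). Its siRNA channel was near background on 1 of 2 arrays in each line, where -0.41 (22Rv1, siRNA 2) and -0.43 (LNCaP, siRNA 1) are bounds. With both channels well above background it read -0.08 (22Rv1, siRNA 1) and -0.55 (LNCaP, siRNA 2). The brightest SMARCA4 probe was also at 0.65 ± 0.56 after SMARCB1 siRNA and 0.53 ± 0.40 after SMARCA2 siRNA in LNCaP (SD, n = 2), where the second probe read -0.32 ± 0.11 and -0.28 ± 0.11.

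**Figure D1:**
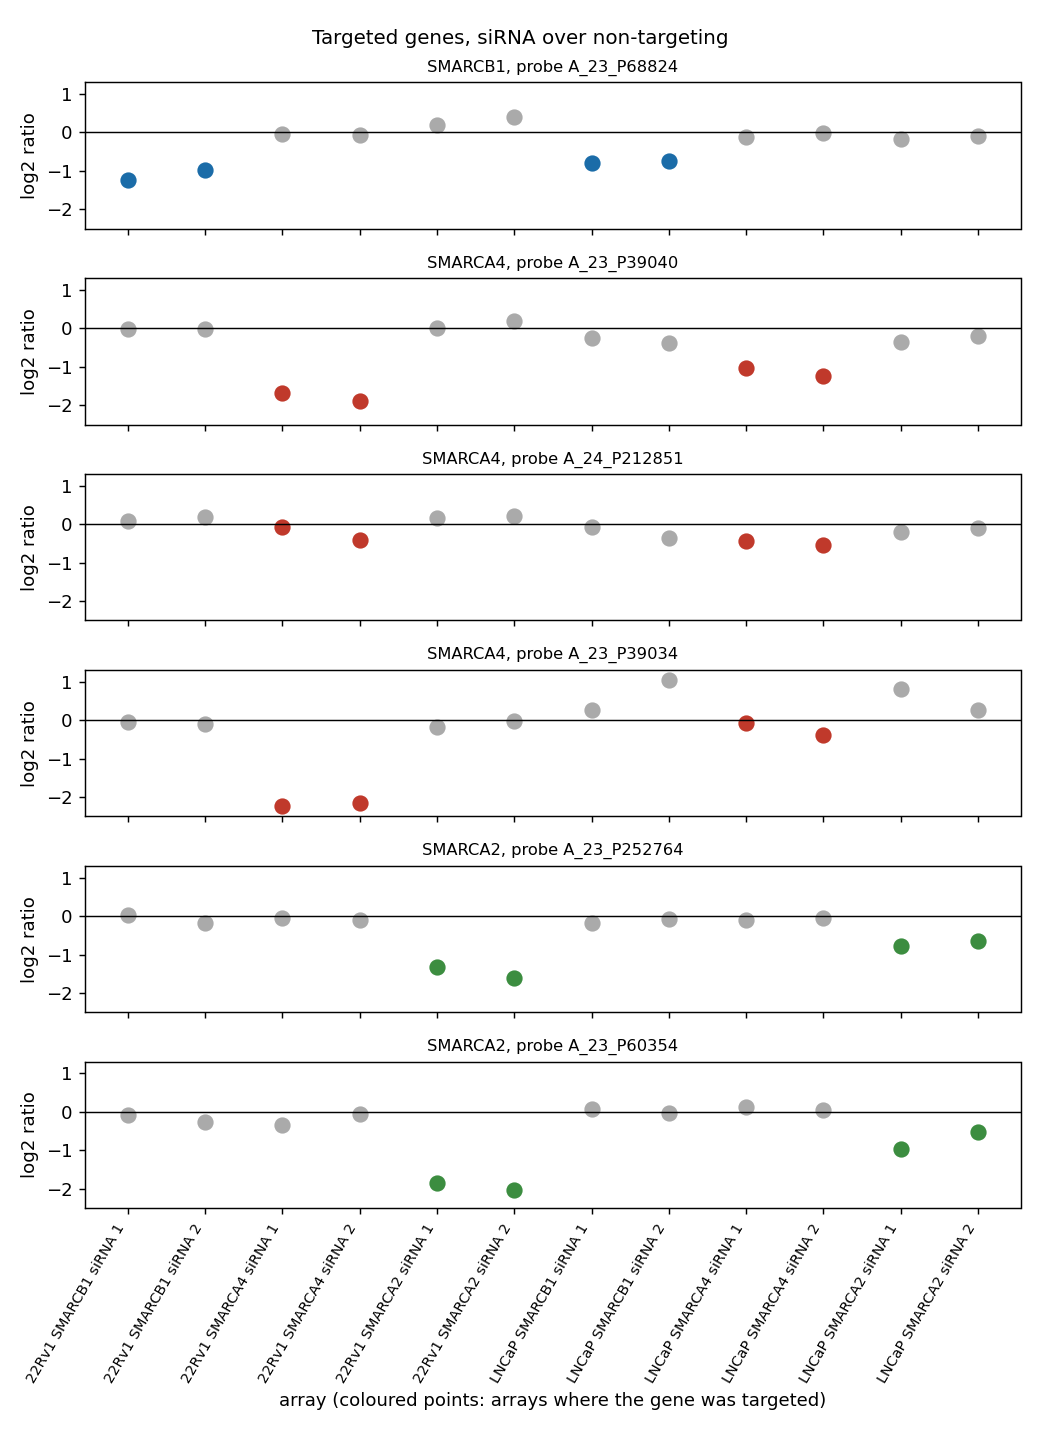
Log2 ratio of siRNA over non-targeting (vertical axis) for each probe of SMARCB1, SMARCA4 and SMARCA2 on each of the 12 arrays (horizontal axis), with arrays where the gene was targeted in colour and the others in grey. The targeted gene is below 0 on every coloured point, from -2.22 to -0.07.

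SMARCB1 knockdown was first examined as the mean of both lines (n = 4 arrays, 2 siRNA sequences each used in both lines). SDC4, a cell-surface proteoglycan, rose by 0.62 ± 0.08, the mucin MUC5B by 0.59 ± 0.08, the small GTPase RAB26 by 0.56 ± 0.07, and NAPSB by 0.66 ± 0.07. MCRIP1 (0.67 ± 0.09, with 1.18 and 0.85 in 22Rv1) and the protease CAPN2 (0.62 ± 0.08) also rose, and read -0.02 and -0.05 with median centring, where the median of all genes was -0.33. MRGPRE and the transcription factor NFATC4 rose by 0.54 each, and DERL3, of the endoplasmic reticulum, by 0.56 ± 0.11. The splicing factor SRSF2 (-0.57 ± 0.08), the interferon-induced IFITM1 (-0.59 ± 0.09), the kinase MAPKAPK5 (-0.58 ± 0.11, with -1.17 on the LNCaP array of siRNA 1) and the ribosomal protein gene RPS2 (-0.63 ± 0.09) fell. The nuclear lamina gene LMNB1 (-1.02 ± 0.24), the replicative helicase subunit MCM6 (-0.61 ± 0.15), DGUOK (-0.83 ± 0.26), IL15 (-0.69 ± 0.20), PSMD10 (-0.65 ± 0.21) and CIAO2A (-0.58 ± 0.14) fell as well. Their largest value lay on the LNCaP array of siRNA 1, where DGUOK read -2.67, PSMD10 -2.15, IL15 -2.07, LMNB1 -1.91 (and -1.56 with siRNA 2), CIAO2A -1.46 and MCM6 -1.22. The pseudogene KRT18P42 (0.80 ± 0.23) read 2.32 on that array and had a median of 0.33 on the others. Other probes of SDC4 and DERL3 (-0.06 each) went the other way, as did 4 of 5 other probes of RPS2. Where a channel was near background, CXCR1 was at least 1.54-fold and C1QTNF4 at least 1.34-fold higher, and FAM13A-AS1 at least 1.45-fold and CA13 at least 1.4-fold lower.

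Of the interferon-stimulated genes, 9 of 26 fell and 1 rose (13 and 1 when adjusted over the list alone), with a median of -0.19. RIGI (-0.38 ± 0.06) and OASL (-0.34 ± 0.06) fell and ISG20 rose by 0.28 ± 0.07. The list was lower than other genes (camera, adjusted p = 0.016), with adjusted p = 0.93 with an estimated correlation. Of 18 genes of the unfolded protein response, 6 rose and 0 fell (6 and 0 when adjusted over the list alone), among them HERPUD1 (0.37 ± 0.08) and XBP1 (0.26 ± 0.07). That list was higher by camera (median 0.15, adjusted p = 0.016, adjusted p = 0.93 with an estimated correlation) but at -0.53 with median centring (all genes -0.33). The call was lost without the 22Rv1 array of siRNA 1 (adjusted p = 0.067) and without the LNCaP array of siRNA 2 (adjusted p = 0.18). Across the 22090 features tested, 2740 were higher and 3660 lower at an adjusted p under 0.05, of which 77 changed at least 1.5-fold. With 1 value per siRNA sequence 4270 passed. The count was 3505 without the 22Rv1 array of siRNA 2, 4244 without the LNCaP array of siRNA 1 and 3246 without that of siRNA 2.

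By line, MCRIP1 (1.01 ± 0.13), HLA-DMB (0.80 ± 0.13) and ALB (0.78 ± 0.15, its other probe 0.37) were higher after SMARCB1 siRNA in 22Rv1 (n = 2). A2ML1 (-0.93 ± 0.09), CSDC2 (-0.86 ± 0.09), KLF14 (-0.82 ± 0.09), TEX19 (-0.78 ± 0.12) and ELAC1 (-0.76 ± 0.14) were lower there. After SMARCA4 and SMARCA2 siRNA in 22Rv1, A2ML1 read -0.66 and -0.77, CSDC2 -0.63 and -0.69, and KLF14 -0.53 and -0.65. TEX19 read -1.04 and -0.14, and ELAC1 -0.13 and -0.36. Of the oxidative phosphorylation genes in 22Rv1, ATP5F1B rose by 0.36 ± 0.07 and was the 1 of 23 past the test, also when adjusted over the list alone. That list was higher (median 0.10, camera adjusted p = 0.02, 0.091 without siRNA 1), with adjusted p = 0.97 with an estimated correlation, and was at -0.46 with median centring (all genes -0.23). In LNCaP the zinc transporter SLC30A4 (-1.19 ± 0.10, its other probe -0.14), LMNB1 (-1.74 ± 0.34), DGUOK (-1.45 ± 0.36), DLST (-1.31 ± 0.19, its other probe -0.54) and DNAJC7 (-1.32 ± 0.26) fell. DGUOK read -2.67 with siRNA 1 and -0.24 with siRNA 2. CD86 (2.06 ± 0.30), CABP7 (1.94 ± 0.34), IRX5 (1.90 ± 0.28), VPS18 (1.82 ± 0.28) and LRRC2 (1.67 ± 0.33) rose most among the genes the naming rule allows, and these 5 probes were also higher after SMARCA4 and SMARCA2 siRNA in LNCaP. The other probes of IRX5 and LRRC2 read 0.03 and 0.05. The unfolded protein response list was higher in LNCaP, with 9 of 18 members past the test and 14 when adjusted over the list alone, among them HERPUD1 (0.70 ± 0.13) and XBP1 (0.58 ± 0.10). Its median was 0.35 (adjusted p = 5.8e-06, and adjusted p = 0.58 with an estimated correlation), or -0.50 with median centring (all genes -0.45). Interferon-stimulated genes were lower in LNCaP, where 11 of 26 fell and 1 rose (12 and 1 when adjusted over the list alone), with ISG15 at -0.81 ± 0.20 and RIGI at -0.61 ± 0.09 (median -0.22, adjusted p = 0.0021, adjusted p = 0.58 with an estimated correlation). Luminal prostate identity genes were higher, with 5 of 17 past the test and 7 when adjusted over the list alone, including TRPS1 (0.46 ± 0.11), but the list was at -0.70 with median centring. Its adjusted p was 0.0092, 0.07 without siRNA 1, and adjusted p = 0.58 with an estimated correlation. The ATF4 list was higher, with 7 of 22 rising and 1 falling (8 and 1 when adjusted over the list alone), among them TRIB3 (0.67 ± 0.10) and SLC7A11 (0.42 ± 0.09), and was at -0.61 with median centring. Its adjusted p was 0.0092, 0.21 without siRNA 2, and adjusted p = 0.76 with an estimated correlation. Ribosomal protein genes (9 of 23 fell and 1 rose, 10 and 1 when adjusted over the list alone) and ribosome biogenesis genes (4 of 23 fell, 4 when adjusted over the list alone) were lower, with adjusted p = 0.0037 and 0.031, the latter 0.49 without siRNA 1. With an estimated correlation these were adjusted p = 0.58 and 0.76. In 22Rv1 3122 features passed the threshold, 1265 without siRNA 1 and 82 without siRNA 2, and in LNCaP 3641, 643 without siRNA 1 and 509 without siRNA 2. With both channels well above background on all arrays they were 1228 and 1719.

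Genes of DNA replication and cell division were lower after SMARCA4 siRNA in the mean of both lines (n = 4 arrays of 2 siRNA sequences). TYMS (thymidylate synthase, -0.66 ± 0.09), MCM3 (replicative helicase, -0.66 ± 0.10), GINS2 (-0.55 ± 0.09) and E2F2 (-0.54 ± 0.11) fell, as did 19 of 24 G1/S genes (23 when adjusted over the list alone). The G1/S median was -0.37 (camera adjusted p = 7.7e-11, adjusted p = 0.56 with an estimated correlation). Of the G2/M genes, 15 of 26 fell (18 when adjusted over the list alone), with the mitotic cyclin gene CCNB1 at -0.44 ± 0.09, DLGAP5 at -0.40 ± 0.10, KIF20A at -0.39 ± 0.08 and TOP2A at -0.39 ± 0.09. The median was -0.29 (adjusted p = 2.7e-08, adjusted p = 0.56 with an estimated correlation). Of the p53 target genes, 10 of 26 rose and 1 fell (14 and 1 when adjusted over the list alone), with PHLDA3 at 0.92 ± 0.12 and the cyclin-dependent kinase inhibitor CDKN1A at 0.56 ± 0.14. GDF15 (0.69 ± 0.09) and FDXR (0.57 ± 0.13) also rose, and read -0.48 and -0.32 with median centring, where the median of all genes was -0.36. The p53 median was 0.18 (adjusted p = 1.2e-05, adjusted p = 0.56 with an estimated correlation), or -0.38 with median centring.

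These cell cycle and p53 values differed between the 2 SMARCA4 siRNA sequences. With siRNA 1 the G1/S median was -0.63 in 22Rv1 and -0.63 in LNCaP, and with siRNA 2 it was -0.15 and -0.19. On the SMARCB1 arrays the G1/S median lay between -0.20 and 0.07 and on the SMARCA2 arrays between -0.07 and 0.12. The G2/M medians were -0.39 and -0.61 with siRNA 1 and -0.07 and -0.12 with siRNA 2, and the p53 medians 0.46 and 0.29 against 0.16 and -0.05. Of the 24 G1/S genes, 23 were lower with siRNA 1 than with siRNA 2 in 22Rv1 and 23 in LNCaP. The second SMARCA4 probe was no lower with siRNA 1 (-1.69 and -1.04) than with siRNA 2 (-1.90 and -1.24). RPS27L, a p53 target, read 1.25 and 0.97 with siRNA 1 against 0.15 and 0.06 with siRNA 2, and LMNB1 read -2.08 and -1.06 against -0.52 and 0.45.

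**Figure D2:**
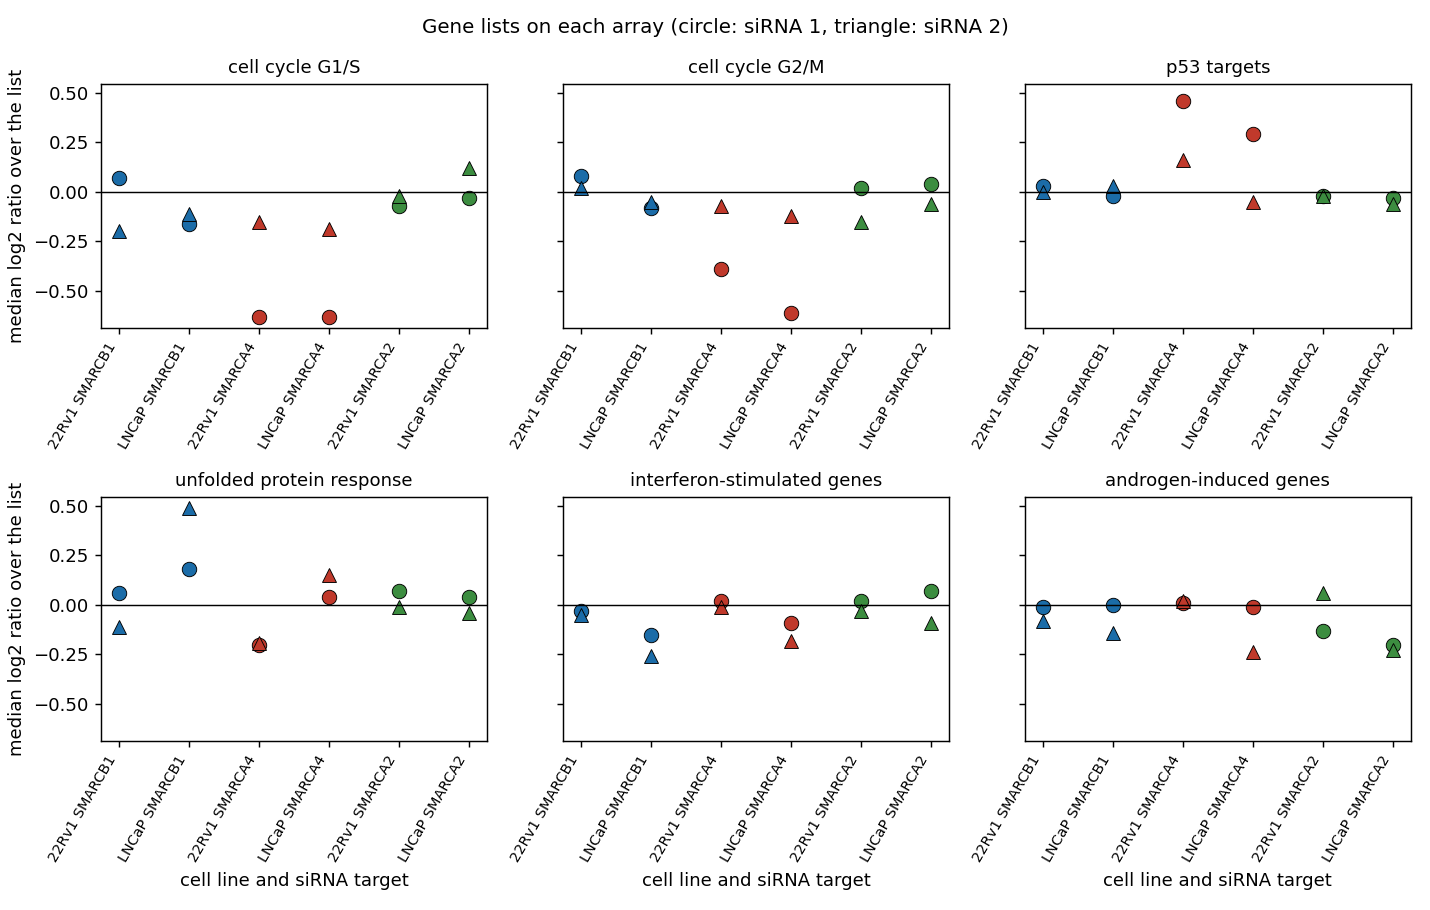
Median log2 ratio over the measured members of 6 gene lists (vertical axis) on each array, by cell line and target (horizontal axis), with circles for siRNA 1 and triangles for siRNA 2. The G1/S median is -0.63 on both arrays of SMARCA4 siRNA 1 and -0.15 and -0.19 on those of siRNA 2.

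Other genes changed with SMARCA4 knockdown. BCHE (-0.79 ± 0.10), RPL22L1 (-0.75 ± 0.12), FAM241A (-0.67 ± 0.10, its other probe -0.15), TEX19 (-0.67 ± 0.08) and the centromere gene CENPU (-0.67 ± 0.13) fell, with RPL22L1 at -1.51 on the 22Rv1 array of siRNA 1 and TEX19 at -1.28 and -0.79 in 22Rv1. GIPR (-0.69 ± 0.09) fell too, but another probe of GIPR read 0. GIPR was lower in LNCaP (-1.20 and -1.30) than in 22Rv1 (-0.07 and -0.20). VPS18 (0.96 ± 0.20), PPP2R5B (0.65 ± 0.11) and FOXS1 (0.57 ± 0.16) rose, with FOXS1 at 1.60 on the LNCaP array of siRNA 1 against a median of 0.17 on the others. VPS18 read 1.84 and 1.53 and HMOX1 1.27 and 0.99 in LNCaP, against 0.30 and 0.16 and 0.15 and 0.28 in 22Rv1. FDXR (1.17) was highest on the 22Rv1 array of siRNA 1. The histone gene H2AC18 (0.72 ± 0.09), the heme oxygenase gene HMOX1 (0.67 ± 0.08), RPS27L (0.61 ± 0.16) and the cyclophilin gene PPIC (0.57 ± 0.08) rose, and read -0.27, -0.18, -0.39 and -0.18 with median centring (all genes -0.36). Near background, NEXN was at least 1.32-fold, FAM13A-AS1 at least 1.27-fold and TEX14 at least 1.23-fold lower. Ribosome biogenesis genes were lower (13 of 23 fell, 13 when adjusted over the list alone, WDR12 at -0.38 ± 0.07 and NPM1 at -0.36 ± 0.05), with adjusted p = 9.1e-05 and adjusted p = 0.56 with an estimated correlation. Heat shock genes were lower (4 of 12 fell, 6 when adjusted over the list alone, the chaperonin genes HSPD1 at -0.53 ± 0.05 and HSPE1 at -0.37 ± 0.06), with adjusted p = 0.027, 0.24 without the 22Rv1 array of siRNA 2, and adjusted p = 0.56 with an estimated correlation. Ribosomal protein genes were lower (10 of 23 fell and 1 rose, 12 and 1 when adjusted over the list alone), with adjusted p = 0.03, 0.26 without the 22Rv1 array and 0.11 without the LNCaP array of siRNA 2, and adjusted p = 0.56 with an estimated correlation. Replication-dependent histones were higher (3 of 13 rose, 5 when adjusted over the list alone) but at -0.56 with median centring, with adjusted p = 0.035, 0.15 without the 22Rv1 array of siRNA 1, and adjusted p = 0.57 with an estimated correlation. Of 22091 features, 1685 were higher and 2128 lower, 57 of them by at least 1.5-fold. With 1 value per siRNA sequence 1432 passed, without background subtraction 6044 and with the SMARCA4 arrays alone 83. The count was 1395 without the 22Rv1 array of siRNA 1, 1761 without that of siRNA 2 and 983 without the LNCaP array of siRNA 1.

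By line, PHLDA3 (1.13 ± 0.17), CDKN1A (0.87 ± 0.19) and DRAM1 (0.79 ± 0.14, its other probes 0.63 and 0.06) rose in 22Rv1, and TEX19 (-1.04 ± 0.12), RPL22L1 (-0.99 ± 0.17), MCM3 (-0.86 ± 0.14) and BCHE (-0.84 ± 0.14) fell (n = 2). GDF15 (0.79 ± 0.13) and FDXR (0.75 ± 0.18) rose there, and read -0.32 and -0.11 with median centring (all genes -0.34). CDKN1A read 1.41 with siRNA 1 and 0.33 with siRNA 2. Unfolded protein response genes were lower in 22Rv1 (4 of 18 fell, 8 when adjusted over the list alone), with MANF at -0.84 ± 0.13 and the chaperone gene HSPA5 at -0.68 ± 0.16 (adjusted p = 0.0088, 0.072 without siRNA 1, adjusted p = 0.74 with an estimated correlation). G1/S genes were lower in 22Rv1 (5 of 24 fell, 16 when adjusted over the list alone, adjusted p = 8.4e-09) and in LNCaP (11 fell, 16 when adjusted over the list alone, adjusted p = 6.3e-09), with adjusted p = 0.74 and 0.43 with an estimated correlation. G2/M genes were lower in 22Rv1 (CENPA at -0.32 ± 0.07 was the 1 of 26 that fell, 8 when adjusted over the list alone, adjusted p = 0.00036, 0.29 without siRNA 1) and in LNCaP (6 fell, 19 when adjusted over the list alone, adjusted p = 6.3e-09), with adjusted p = 0.74 and 0.43 with an estimated correlation. The p53 targets were higher in 22Rv1 (5 of 26 rose, 14 when adjusted over the list alone, adjusted p = 1e-08), with adjusted p = 0.57 with an estimated correlation. Ribosome biogenesis genes were lower in 22Rv1 (NCL at -0.38 ± 0.09 was the 1 of 23 that fell, 10 fell and 1 rose when adjusted over the list alone, adjusted p = 0.011, 0.058 without siRNA 2) and LNCaP (5 fell, 10 when adjusted over the list alone, adjusted p = 5.7e-05), with adjusted p = 0.74 and 0.43 with an estimated correlation. In LNCaP the snoRNA gene SNORD22 (-0.95 ± 0.09), MRPL10 (-0.86 ± 0.18), FAM241A (-0.90 ± 0.14) and TM4SF1 (-0.85 ± 0.12) fell and GIPR read -1.25 ± 0.13. The other probes of MRPL10, FAM241A and GIPR read -0.03, -0.20 and 0.08. CD86 (2.02 ± 0.30), LRRC2 (1.89 ± 0.33), PPM1F (1.79 ± 0.27), VPS18 (1.68 ± 0.28) and CABP7 (1.62 ± 0.34) rose, with other probes of LRRC2 and PPM1F at -0.08 and 0.01. Heat shock genes (4 of 12 fell, 4 when adjusted over the list alone, adjusted p = 0.033, 0.074 without siRNA 1) and ribosomal protein genes (7 of 23 fell and 1 rose, 9 and 1 when adjusted over the list alone, adjusted p = 0.0048, 0.14 without siRNA 2) were lower in LNCaP. Histones were higher there (3 of 13 rose, 5 when adjusted over the list alone, adjusted p = 0.0048) but at -0.58 with median centring (all genes -0.42), and each of these 3 lists had adjusted p = 0.43 with an estimated correlation. In 22Rv1 616 features passed the threshold, 0 without siRNA 1 and 333 without siRNA 2, where the limma count at an unadjusted p under 0.05 with both was 5019. In LNCaP 1847 passed, and 117 without siRNA 1. The 22Rv1 count was 3334 with Agilent ratios, 3674 without background subtraction and 38 with an offset of 16. The LNCaP count was 390 with Agilent ratios, 1107 with an offset of 16 and 0 with the arrays of that group alone (5899 at an unadjusted p under 0.05 by limma with all arrays).

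After SMARCA2 siRNA, as the mean of both lines (n = 4 arrays of 2 siRNA sequences), the ribosomal protein genes RPS27 (-0.74 ± 0.06, its other probe -0.28), RPS20 (-0.69 ± 0.15) and RPS2 (-0.69 ± 0.09) were lower, although 2 of 5 other probes of RPS2 went the other way. The kinase gene MAP3K20 (-0.78 ± 0.13), the KIT ligand gene KITLG (-0.61 ± 0.08), the cytochrome c gene CYCS (-0.60 ± 0.08) and CYP4V2 (-0.67 ± 0.14) fell, as did GIPR (-0.68 ± 0.09), whose other probe read 0. Other probes read -0.19 for MAP3K20, -0.17 and -0.13 for CYCS and -0.37 and -0.12 for CYP4V2. RPS27, RPS20, RPS2 and CYCS were also lower after SMARCB1 (-0.55, -0.35, -0.63 and -0.38) and SMARCA4 siRNA (-0.54, -0.62, -0.61 and -0.57). None of these was called in a difference between targets. MIDN (0.65 ± 0.16), CD3E (0.51 ± 0.04) and VPS18 (0.97 ± 0.20) rose. HMOX1 (0.63 ± 0.08), PXMP4 (0.53 ± 0.07), the sterol reductase gene TM7SF2 (0.48 ± 0.10) and PLA2G4B (0.47 ± 0.08) rose, and read -0.09, -0.05, -0.36 and -0.20 with median centring (all genes -0.34). IGKV2-24 (0.64 ± 0.07), C1QTNF5 (0.50 ± 0.05) and PGS1 (0.48 ± 0.05) rose. Both LNCaP arrays lay above both 22Rv1 arrays for VPS18 (2.43 and 1.04), IGKV2-24 (1.40 and 1.01), PXMP4 (1.14 and 0.83), C1QTNF5 (0.92 and 0.90) and PGS1 (0.91 and 0.76). Near background, NAP1L3 was at least 1.53-fold, FAM13A-AS1 at least 1.39-fold and FRMD6 at least 1.38-fold lower. The metal-binding metallothioneins were lower, with 6 of 9 falling (9 when adjusted over the list alone), MT1H at -0.36 ± 0.08 and MT2A at -0.29 ± 0.08. Their median was -0.23 (adjusted p = 0.0047, 0.054 without the 22Rv1 array of siRNA 2, adjusted p = 0.89 with an estimated correlation). Of 22091 features, 1954 were higher and 2701 lower, 38 of them by at least 1.5-fold. With 1 value per siRNA sequence 2247 passed. Without the 22Rv1 array of siRNA 1 there were 2274, without the LNCaP array of siRNA 1 1711 and without that of siRNA 2 1204.

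In 22Rv1 (n = 2), HNRNPCL1 (0.82 ± 0.13), SHH (0.70 ± 0.12), MRGPRE (0.70 ± 0.09), GNG8 (0.69 ± 0.16) and POLR2A (0.65 ± 0.08, but its other probe -0.27) were higher after SMARCA2 siRNA. The probes that rose also read 0.51 to 0.67 after SMARCB1 siRNA and 0.31 to 0.51 after SMARCA4 siRNA in 22Rv1. None of them was called in a difference between targets. CYP4V2 (-1 ± 0.19), the EGF-family ligand AREG (-0.94 ± 0.24), MAP3K20 (-0.91 ± 0.18) and DYNC1LI2 (-0.85 ± 0.21) were lower, with other probes at -0.44 and -0.20 for CYP4V2, -0.17 for MAP3K20 and -0.40 and -0.25 for DYNC1LI2. In LNCaP, SPON2 (-0.86 ± 0.10), EAF2 (-0.85 ± 0.09) and the phosphatase gene DUSP1 (-0.76 ± 0.07) fell, and RPS2 read -0.77 ± 0.12 and GIPR -1.10 ± 0.13. CD86 (2.00 ± 0.30), LRRC2 (1.96 ± 0.33), IRX5 (1.90 ± 0.28), CABP7 (1.79 ± 0.34) and PPM1F (1.77 ± 0.27) rose, with other probes of LRRC2, IRX5 and PPM1F at -0.05, 0.14 and -0.26. Androgen-induced genes were lower in LNCaP, where KLK2, a kallikrein gene induced by androgen, fell by 0.71 ± 0.13 (its other probe read -0.44), ELL2 by 0.49 ± 0.10 and NCAPD3 by 0.40 ± 0.07. These were the 3 of 30 past the test, 11 when adjusted over the list alone (median -0.24, adjusted p = 0.00015, adjusted p = 0.53 with an estimated correlation). The androgen-induced KLK3 was not among them, at 0.04 on the LNCaP array of siRNA 1. Ribosomal protein genes were lower in LNCaP (6 of 23 fell and 0 rose, 13 and 1 when adjusted over the list alone, adjusted p = 4e-06, adjusted p = 0.53 with an estimated correlation), as were metallothioneins (MT1H at -0.46 ± 0.11 was the 1 of 9 that fell, 2 when adjusted over the list alone, adjusted p = 0.0019, adjusted p = 0.55 with an estimated correlation). The ATF4 list was higher (2 of 22 rose, 4 when adjusted over the list alone, adjusted p = 0.0019, adjusted p = 0.58 with an estimated correlation), with TRIB3 at 0.52 ± 0.10 and SLC7A11 at 0.44 ± 0.09, but at -0.51 with median centring (all genes -0.40). In 22Rv1 0 of the 35 lists were called by camera and 4 by fry. In 22Rv1 4471 features passed the threshold, 1046 without siRNA 1 and 2047 without siRNA 2, and in LNCaP 505, 41 without siRNA 1 and 122 without siRNA 2. With array weights these were 2302 and 2443.

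**Figure D3:**
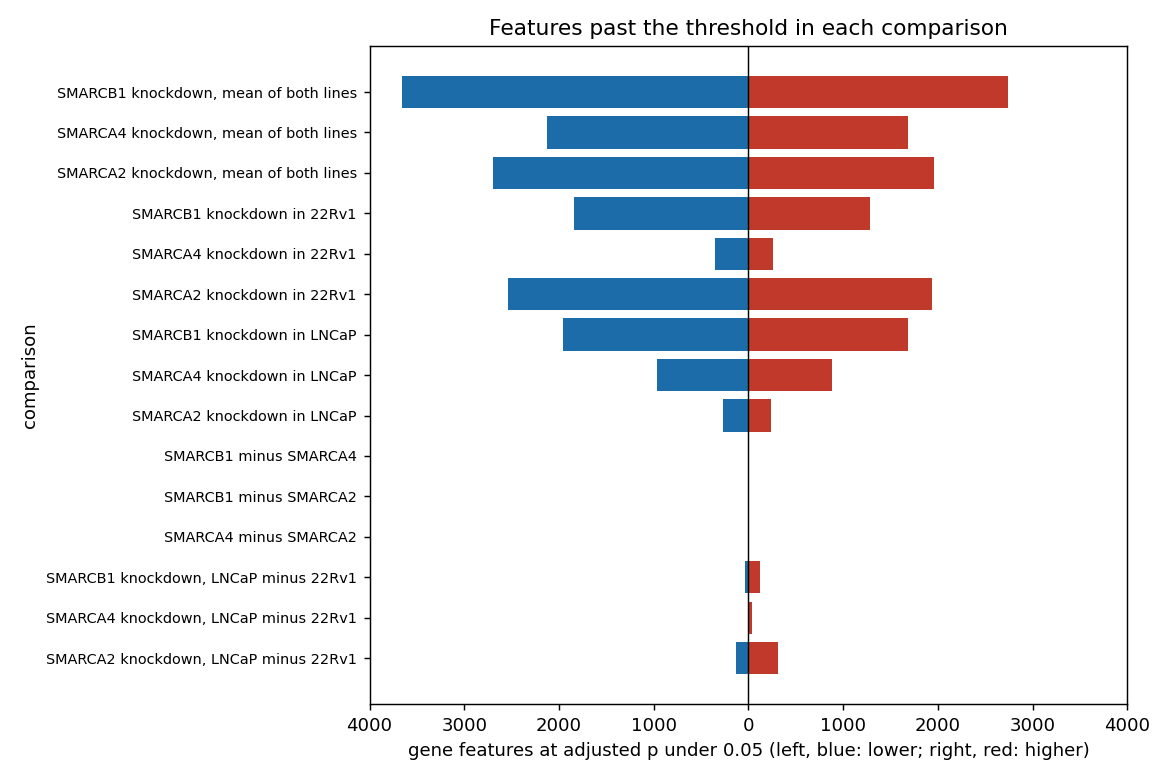
Number of gene features at an adjusted p under 0.05 (horizontal axis, lower to the left and higher to the right) in each comparison (vertical axis). Means of both lines have 3813 to 6400 features and differences between targets 2 to 4.

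The features called for the means of the 3 targets overlapped. Of the features tested, 1483 passed the threshold for all 3 targets, of which 642 were higher in all and 840 lower in all. Some genes named above for 1 target read alike after SMARCB1, SMARCA4 and SMARCA2 siRNA. Examples are SDC4 (0.62, 0.45 and 0.43), SRSF2 (-0.57, -0.62 and -0.42) and HMOX1 (0.33, 0.67 and 0.63), while IL15 (-0.69, -0.04 and 0.12) did not. The IL15 mean after SMARCB1 siRNA rested on the LNCaP array of siRNA 1 (-2.07). The other arrays of that target read -0.38, -0.13 and -0.19, and IL15 was not called in a difference between targets. For SMARCB1 and SMARCA4, 940 were higher and 1225 lower in both, where 20 simulations of unchanged groups against a shared control gave 193 and 205 and independent lists would give 209 and 353. The simulated genes were independent and held no dye effect. The simulated control had the spread of a single array, and that of the real control is unknown. For SMARCB1 and SMARCA2 the numbers were 1226 and 1650, against 194 and 210 simulated and 242 and 448 independent. For SMARCA4 and SMARCA2 they were 837 and 1069, against 196 and 205 simulated and 149 and 260 independent. Within a line the overlap lay below the simulated one in 4 of 6 pairs. These were SMARCB1 and SMARCA4 in 22Rv1 (148 and 163 against 203 and 202), SMARCA4 and SMARCA2 in 22Rv1 (165 and 204 against 197 and 208) and in LNCaP (168 and 178 against 208 and 209), and SMARCB1 and SMARCA2 in LNCaP (165 and 190 against 205 and 211). It lay above for SMARCB1 and SMARCA2 in 22Rv1 (780 and 942 against 200 and 205) and SMARCB1 and SMARCA4 in LNCaP (383 and 510 against 205 and 207). Overlap grows with the number of features called. The 4 pairs below each held a group with few, SMARCA4 in 22Rv1 (616) or SMARCA2 in LNCaP (505). For the means, correlations across genes, which are not independent replicates, were 0.62, 0.69 and 0.64 where the simulation gave 0.66, 0.67 and 0.67, and the covariance exceeded the simulated one by 0.00812, 0.00978 and 0.00639. The labels name 1 control replicate and do not say whether it was 1 RNA in each line, so the control could not be split. Part of the excess may come from a control that strayed more than the simulated one, and a dye effect of a gene enters all 12 ratios alike.

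Differences between targets, in which the dye effect cancels, and the control too if it was 1 RNA in each line, held few single genes. SNORD22 (0.71 ± 0.09, adjusted p = 0.049) and the neuronal adhesion gene CNTNAP2 (0.57 ± 0.08, adjusted p = 0.049) were higher after SMARCB1 than after SMARCA4 siRNA, and the other features among the 4 called were SMARCA4 and SMARCB1, named after their values were seen. SNORD22 and CNTNAP2 were not called with siRNA number as a block (adjusted p = 0.085 each), siRNA sequence as a random block (0.12 each) or slide as a random block (0.2 each). In 22Rv1, where both targets shared a slide, SNORD22 read 0.25 after SMARCB1 and 0.03 after SMARCA4 siRNA. In LNCaP, where they lay on different slides, it read 0.25 and -0.95. After SMARCA2 siRNA it read 0.21 in 22Rv1 and -0.61 in LNCaP, there on the slide of SMARCA4. Slide and target therefore cannot be told apart for the SNORD22 difference in LNCaP. CNTNAP2 read 0.50 and 0.35 after SMARCB1 siRNA in 22Rv1 and -0.38 and -0.37 after SMARCA4 siRNA, but -0.06 and -0.40 on average in LNCaP. The other CNTNAP2 probe gave a difference of -0.12 (-0.13 after SMARCB1 and -0.01 after SMARCA4 siRNA). SMARCA2 was 1.28 ± 0.11 higher after SMARCB1 than after SMARCA2 siRNA (adjusted p = 0.00074), with SMARCB1 as the other of 2 called. SMARCA2 was also 1.29 ± 0.11 higher after SMARCA4 than after SMARCA2 siRNA (adjusted p = 0.0013), with SMARCA4 as the other of 2. At an unadjusted p under 0.05, limma gave 2948, 2509 and 2227 features. Without the LNCaP array of SMARCA4 siRNA 2 the counts for SMARCB1 minus SMARCA4 and SMARCA4 minus SMARCA2 were 744 and 638, and without the 22Rv1 array of SMARCA4 siRNA 1 they were 0 and 1. Without the 22Rv1 array of SMARCA4 siRNA 2 they were 16 and 22. For SMARCB1 minus SMARCA4 the count was 70 without the LNCaP array of SMARCB1 siRNA 2 and 2 without that of siRNA 1, and for SMARCA4 minus SMARCA2 it was 1 without the 22Rv1 array of SMARCA2 siRNA 2. For SMARCB1 minus SMARCA2 it was 76 without the LNCaP and 5 without the 22Rv1 array of SMARCB1 siRNA 2, 7 without the 22Rv1 array of SMARCB1 siRNA 1. It was 14 without the 22Rv1 array of SMARCA2 siRNA 1, and 4 and 7 without the LNCaP arrays of SMARCA2 siRNA 1 and 2.

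Camera with the preset correlation called 8 lists for SMARCB1 minus SMARCA4, 7 for SMARCB1 minus SMARCA2 and 10 for SMARCA4 minus SMARCA2, where camera with an estimated correlation and fry each called 0. G1/S genes were lower after SMARCA4 than after SMARCA2 siRNA (median -0.42, 0 of 24 past the test and 20 when adjusted over the list alone, adjusted p = 3.7e-17, adjusted p = 0.44 with an estimated correlation), and -0.46 in LNCaP, where both targets share a slide. They were also 0.30 higher after SMARCB1 than after SMARCA4 siRNA (adjusted p = 3.3e-10, adjusted p = 0.59 with an estimated correlation), and 0.33 in 22Rv1 on 1 slide. The p53 targets were 0.22 higher after SMARCA4 than after SMARCA2 siRNA (adjusted p = 2.3e-09, adjusted p = 0.44 with an estimated correlation), and unfolded protein response genes 0.25 higher after SMARCB1 than after SMARCA4 siRNA (adjusted p = 1.7e-06, adjusted p = 0.59 with an estimated correlation). Interferon-stimulated genes were lower after SMARCB1 than after SMARCA2 siRNA (median -0.11, adjusted p = 0.00069, adjusted p = 0.6 with an estimated correlation). The list tests on differences were chosen after the data were seen, and the G1/S and p53 medians lay farther from 0 on the SMARCA4 siRNA 1 arrays than on the siRNA 2 arrays.

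Differences between the lines were tested for each target. Depletion was weaker in LNCaP than in 22Rv1 for SMARCA2 (-0.75 against -1.93) and by the second SMARCA4 probe (-1.14 against -1.79). The third SMARCA4 probe went the other way (-0.49 against -0.24), and the SMARCB1 values (-0.76 against -1.11) are bounds. Depth of depletion and cell line therefore cannot be told apart in these differences. The dye effect cancels in them, but the non-targeting control of each line does not, and the test leaves out its spread. If it was 1 RNA, a control that strayed would enter the line differences of all 3 targets alike. A call for all 3 targets may therefore not be 3 independent results. Across genes the line differences of the targets correlated at 0.37 to 0.52. The keratin gene KRT80 was higher in LNCaP than in 22Rv1 by 1.21 ± 0.18 after SMARCB1, 1.11 ± 0.18 after SMARCA4 and 1.27 ± 0.18 after SMARCA2 siRNA, and was 1 of 29 features called for all 3 targets. The other KRT80 probe gave -0.20, 0.20 and -0.07 and read 0.02 on average in LNCaP. KLK2 (-1.20 ± 0.18, its other probe -0.39) and SPON2 (-0.88 ± 0.14) were lower in LNCaP after SMARCA2 siRNA, and SNORD22 after SMARCA4 (-0.98 ± 0.13) and SMARCA2 siRNA (-0.82 ± 0.13). ALB (-1.08 ± 0.21, its other probe -0.05) and EMD (-1.17 ± 0.18), which encodes the nuclear envelope protein emerin, were lower in LNCaP after SMARCB1 siRNA. After SMARCB1 siRNA 163 features differed, 16 and 4 without the 22Rv1 arrays of siRNA 1 and 2 and 0 without the LNCaP array of siRNA 1, with 3451 at an unadjusted p under 0.05 in the limma fit of all arrays. After SMARCA4 siRNA 47 differed, 0 without the 22Rv1 or LNCaP array of siRNA 1, 19 without the 22Rv1 array of siRNA 2 and 892 without the LNCaP array of siRNA 2 (2742 at an unadjusted p under 0.05 by limma with all arrays). After SMARCA2 siRNA 437 differed, 227 and 75 without the 22Rv1 arrays and 8 and 121 without the LNCaP arrays of siRNA 1 and 2. With siRNA sequence as a random block the 3 counts were 448, 134 and 1005, with Agilent ratios the last 2 were 251 and 696, and without background subtraction they were 100, 115 and 189. Slide 2 alone held arrays of both lines, of a different target in each, so a slide effect could not be fitted in these differences. On that slide KRT80 read -0.11 on average in 22Rv1 (SMARCA2 siRNA) and 1.03 in LNCaP (SMARCB1 siRNA). Unfolded protein response genes were 0.40 higher in LNCaP after SMARCB1 siRNA (1 of 18 past the test, 10 when adjusted over the list alone, adjusted p = 2.1e-05, adjusted p = 0.77 with an estimated correlation).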

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

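Of the tests in this part, those of the slide and of both RNAs for the LNCaP features, and the gene-list tests of line differences, were chosen after the results were seen. Each result here differed between LNCaP and 22Rv1 by a limma or camera test of the difference itself, and values are LNCaP minus 22Rv1 on the log2 scale. SMARCA2, and SMARCA4 by its second probe, were less depleted in LNCaP, so depth of depletion and line cannot be told apart. The control of each line does not cancel in these values either, so differences shared by targets may come from it.

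After SMARCB1 siRNA 163 features differed, after SMARCA4 siRNA 47 and after SMARCA2 siRNA 437. For SMARCB1, VPS18 (2.00), CD86 (2.53), TNRC6B (1.58), RPRD1B (1.51), KRT80 (1.21), DLG4 (1.13), KLF14 (1.03), CSDC2 (0.92), A2ML1 (0.89) and TEX19 (0.84) were higher in LNCaP, and EMD (-1.17), PFDN6 (-1.16), ALB (-1.08), PRPS1L1 (-1.04), PRPS1 (-0.93) and SLC30A4 (-0.85) lower. For SMARCA4, the brightest SMARCA4 probe (1.96), KRT80 (1.11), TMED9 (1.09), TLL2 (1.05) and IGKV2-24 (1.04) were higher, and GIPR (-1.11) and SNORD22 (-0.98) lower. For SMARCA2, LRRC2 (2.47), CD86 (2.46), CABP7 (2.13), PPM1F (2.03), IRX5 (2.00), PKD1L2 (1.32), PGF (1.28), KRT80 (1.27), RAPH1 (1.26), SMARCA2 itself (1.18), IGKV2-24 (1.13), PXMP4 (0.91), C1QTNF5 (0.83), HMOX1 (0.71) and PGS1 (0.70) were higher, and KLK2 (-1.20), SPON2 (-0.88), HNRNPCL1 (-0.88), GIPR (-0.85), SNORD22 (-0.82), MRGPRE (-0.68), EAF2 (-0.60) and DUSP1 (-0.50) lower. Other probes of these genes, where there were any, gave for SMARCB1 -0.20 (KRT80), 0.03 (DLG4), -0.05 (ALB), 0 (SLC30A4), -1.86 (PRPS1), and 0.44, 0.22 and 0.50 (TNRC6B). For SMARCA4 they gave 0.65 and -0.24 (SMARCA4), 0.20 (KRT80) and 0.15 (GIPR). For SMARCA2 they gave 0.39 (LRRC2), -0.09 (PPM1F), 0.26 (IRX5), -0.07 (KRT80), -0.07 (RAPH1), 0.76 (SMARCA2), -0.58 (PGS1), -0.39 (KLK2), -0.52 (HNRNPCL1) and -0.07 (GIPR).

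Of the gene lists after SMARCB1 siRNA, the unfolded protein response (0.40), the ATF4 list (0.25, with TRIB3 at 0.80 ± 0.15) and luminal identity genes (0.14, but -0.30 with median centring, all genes -0.19) were higher in LNCaP by camera with the preset correlation (adjusted p = 0.77, 0.77 and 0.69 with an estimated correlation). Oxidative phosphorylation (-0.16) and ribosomal protein genes (-0.11) were lower (adjusted p = 0.69 and 0.77 with an estimated correlation). After SMARCA4 siRNA the unfolded protein response (0.21) and histones (0.09, but -0.13 with median centring, all genes -0.01) were higher, and p53 targets (-0.23) and G2/M genes (-0.11) lower (adjusted p = 0.68, 0.68, 0.68 and 0.81 with an estimated correlation). After SMARCA2 siRNA androgen-induced genes (-0.20) and ribosomal protein genes (-0.14) were lower (adjusted p = 0.99 each with an estimated correlation).

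Some of the rises in LNCaP may come from a set of probes whose signal was not that of the gene. On average over the 6 LNCaP arrays 20 features, among them CD86, LRRC2, CABP7, IRX5 and VPS18, were more than 1 log2 higher, and they moved together with a median correlation of 0.81 over these arrays. Other probes of 5 of these genes had a median of 0.05 (-0.14 to 0.05 for LRRC2, IRX5, KRT80 and PPM1F, but 0.19 to 0.46 for TNRC6B), and the other features had no second probe to check. The median of the non-targeting channel of these probes was also 1.48 higher in LNCaP than in 22Rv1, as a sequence present in both LNCaP RNAs would give, but the channel was not higher for 4 of 20, including KRT80, IGKV2-24 and IRX5, what the sequence is stays open and no biological explanation was tested. Against position on the slide, the spots lay 1.19 times as far apart as random sets, and against slide, the 22Rv1 arrays of slide 2 were at -0.16 where the LNCaP arrays of that slide were at 1.47.

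The same signal may reach the brightest SMARCA4 probe, which lay above the second SMARCA4 probe in LNCaP. Over the 6 LNCaP arrays the gap between both probes went with the mean of the set (Pearson r 0.90, exact permutation p = 0.021, Spearman rho 0.89, exact permutation p = 0.033, both two-sided). Without the 2 arrays farthest from the median r was 0.98. The second probe read -1.14 ± 0.14 after SMARCA4 siRNA in LNCaP (SD, n = 2).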

How the results depend on the processing

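Signal over background and 2 arrays per group limit these results. Median centring moved the median of all genes to -0.35 from -0.02 because, in place of loess, it leaves the intensity trend in the ratios. Counts against the non-targeting channel grew with it. Aquantile scaling between arrays alters intensities and leaves the log2 ratios, so it could act only through the choice of probe and could not test the ratios. With it 22 of 22 counts and targeted genes stayed on their side of the threshold and within 1.5 times their size. For other changes the cause was not tested. The slide block could not be fitted for single lines and line differences, where slide is nested with line and group. The list tests with the Agilent ratios, those on differences, the additive fit without a slide block and the fits by siRNA sequence were chosen after the data were seen.

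With median centring the counts of the means were 17876 (SMARCB1), 17900 (SMARCA4) and 17905 (SMARCA2). They were in 22Rv1 12968, 14594 and 15357, in LNCaP 17969, 17553 and 17230, for line differences 4595, 1983 and 2303, and for SMARCB1 minus SMARCA4 1. There 185 lists were called. SMARCA4 in LNCaP was at -1.21. Below 0 there, where the medians of all genes were -0.33, -0.36 and -0.34 in the means, were MCRIP1 (-0.02) and CAPN2 (-0.05) for SMARCB1. So were H2AC18 (-0.27), GDF15 (-0.48, 22Rv1 -0.32), HMOX1 (-0.18), RPS27L (-0.39), PPIC (-0.18) and FDXR (-0.32, 22Rv1 -0.11) for SMARCA4. For SMARCA2 they were HMOX1 (-0.09), PXMP4 (-0.05), TM7SF2 (-0.36) and PLA2G4B (-0.20). Of these only GDF15 in the mean, RPS27L and TM7SF2 lay below the median of all genes. Lists that camera, which compares with other genes, put higher before and lower there were past its threshold for oxidative phosphorylation (-0.46, all genes -0.23), luminal identity in LNCaP (-0.70, all genes -0.45) and histones (mean -0.56, LNCaP -0.58, all genes -0.36 and -0.42). They were not past it for the unfolded protein response (SMARCB1 mean -0.53, LNCaP -0.50, all genes -0.33 and -0.45), ATF4 (SMARCB1 LNCaP -0.61, SMARCA2 LNCaP -0.51, all genes -0.45 and -0.40), p53 targets (-0.38, all genes -0.36) and the line differences of luminal identity (-0.30, all genes -0.19) and histones (-0.13, all genes -0.01).

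With Agilent processed ratios the counts were 3334 (SMARCA4 in 22Rv1), 390 (SMARCA4 in LNCaP). They were 251 and 696 (line differences of SMARCA4 and SMARCA2), 1, 4 and 0 (SMARCB1 minus SMARCA4, SMARCB1 minus SMARCA2, SMARCA4 minus SMARCA2), and 20 lists. With the deposited table they were 3336, 390, 254, 678, 1, 4 and 0 for the same comparisons. Without background subtraction SMARCA4 had 6044 in the mean and 3674 in 22Rv1, SMARCA2 835 in LNCaP, the line differences 100, 115 and 189, SMARCB1 minus SMARCA2 4 and SMARCA4 minus SMARCA2 1. With an offset of 16, SMARCA4 had 38 in 22Rv1 and 1107 in LNCaP, line differences 81 (SMARCB1) and 0 (SMARCA4), and SMARCA4 minus SMARCA2 1.

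With both channels well above background on all 12 arrays, so fewer genes, the counts were 3103 and 2762 (SMARCB1 and SMARCA2 means), 1228, 1007 and 2121 (22Rv1), 1719 (SMARCB1 in LNCaP). They were 98 and 169 (line differences of SMARCA4 and SMARCA2) and 1 (SMARCB1 minus SMARCA2). Another GIPR probe replaced the first there, at 0 in the SMARCA4 mean, 0.08 in LNCaP and 0.15 for the line difference. Without a filter SMARCA4 in 22Rv1 had 314 and the SMARCA2 line difference 271. SMARCA4 read -0.62 in LNCaP as the mean of its probes, -1.14 with the second probe and -0.49 with the third, which gave -0.24 in 22Rv1.

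With array weights the counts were 2002 and 2302 (SMARCB1 and SMARCA2 in 22Rv1), 2443 (SMARCA2 in LNCaP), 89 (SMARCB1 line difference) and 1 (SMARCA4 minus SMARCA2). With trend and robust moderation the SMARCA4 line difference had 71 and SMARCA4 minus SMARCA2 1. With the arrays of each comparison alone, so fewer samples, there were 83 (SMARCA4 mean), 2731 and 2379 (SMARCA2 in 22Rv1 and LNCaP), 0 (SMARCA4 in LNCaP). They were 75, 11 and 117 (line differences), 0 (SMARCB1 minus SMARCA4) and 4 (SMARCB1 minus SMARCA2). At 1.5-fold as well there were 77, 57 and 38 (means), 147, 53 and 221 (22Rv1), 270, 271 and 107 (LNCaP), and 236 (SMARCA2 line difference). With an estimated correlation 0 lists were called by camera and with fry 44.

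With the siRNA number as a replicate block (paired over groups) SMARCB1 minus SMARCA4 had 2 and SMARCA4 minus SMARCA2 1. With slide as a random block 0 were called in SMARCB1 minus SMARCA4, SMARCB1 minus SMARCA2 and SMARCA4 minus SMARCA2, and with the same terms without it 0, 1 and 0. With siRNA sequence as a random block (consensus correlation 0.18) there were 2536 (SMARCA4 mean), 2 and 1 (SMARCB1 minus SMARCA4 and SMARCA4 minus SMARCA2) and 448, 134 and 1005 (line differences). With 1 value per siRNA sequence there were 1432 and 2247 (SMARCA4 and SMARCA2 means) and 1 (SMARCB1 minus SMARCA4). Within 1 slide SMARCB1 minus SMARCA4 had 2 and SMARCA4 minus SMARCA2 0.

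Leaving out 1 array, which assumes that a lone array varies like the other groups, gave 3246 to 6739 (SMARCB1 mean), 983 to 3389 (SMARCA4 mean), 1204 to 4863 (SMARCA2 mean). By line it gave 82 to 3336, 0 to 720 and 1046 to 4670 (22Rv1), 509 to 3935, 117 to 1970 and 41 to 620 (LNCaP). Differences ranged over 0 to 744 (SMARCB1 minus SMARCA4), 2 to 76 (SMARCB1 minus SMARCA2), 1 to 638 (SMARCA4 minus SMARCA2), 0 to 224, 0 to 892 and 8 to 474 (line differences) and 31 to 38 lists. The targeted genes ranged from -1.25 to -0.97 and -0.79 to -0.74 (SMARCB1 in 22Rv1 and LNCaP), -2.22 to -2.16 and -0.39 to -0.07 (SMARCA4), and -2.02 to -1.85 and -0.97 to -0.53 (SMARCA2).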

Other observations

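Of the tests in this part, those of the non-targeting RNA, of the dye or control for the cell cycle genes, of SMARCA4 siRNA 1 against siRNA 2, and of siRNA sequences across lines were chosen after the results were seen. The naming rule, the 35 lists and the other tests were set before the data were examined, and 1 of these earlier tests was read differently afterwards, as stated with it.

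Some genes of lists that camera did not call were past the limma threshold in the means of both lines. Fry called 5, 9 and 7 of 35 lists for the SMARCB1, SMARCA4 and SMARCA2 means, where camera called 2, 7 and 1. Among those that camera did not call, and not the only ones, were the neuroendocrine and neuronal genes as higher (fry adjusted p = 0.025 for SMARCB1, 0.042 for SMARCA4 and 0.032 for SMARCA2). The immediate early genes were called as lower by fry (adjusted p = 0.019 for SMARCA4 and 0.012 for SMARCA2). Fry tests members against 0 and not against other genes, so a dye or control effect common to the targets could give such calls. In differences between targets, tested after the data were seen, fry called neither list. The neuroendocrine and neuronal medians there were 0.01, 0.01 and 0 (fry adjusted p = 0.84, 0.96 and 0.82). HOXD9, a homeobox gene, fell after SMARCB1 (-0.59 ± 0.05), SMARCA4 (-0.35 ± 0.05) and SMARCA2 siRNA (-0.36 ± 0.05). The mesenchymal transcription factor gene SNAI2 fell after SMARCB1 (-0.41 ± 0.07) and SMARCA2 siRNA (-0.40 ± 0.07). UCHL1 (-0.46 ± 0.07) and KDM6B (-0.50 ± 0.09), a histone demethylase gene, fell after SMARCB1 siRNA, EZH2 (-0.35 ± 0.08) and MYC (-0.35 ± 0.08) after SMARCA4 siRNA, and USP18 (-0.58 ± 0.12) and TGFB2 (-0.44 ± 0.09) after SMARCA2 siRNA. The SWI/SNF subunit gene ARID1A fell after SMARCA4 (-0.33 ± 0.06) and SMARCA2 siRNA (-0.36 ± 0.06). Rises were at least as frequent in some lists: after SMARCB1 siRNA 6 of 18 neuroendocrine and neuronal genes rose and 2 fell, 4 and 2 of 21 Polycomb genes, and 4 and 4 of 22 HOX genes. Over all features 29% were called after SMARCB1, 17.3% after SMARCA4 and 21.1% after SMARCA2 siRNA, so any list would hold some called members. ENO2 rose after SMARCB1 (0.32 ± 0.05), SMARCA4 (0.45 ± 0.05) and SMARCA2 siRNA (0.29 ± 0.05), CHGA after SMARCB1 (0.32 ± 0.05) and SMARCA2 siRNA (0.27 ± 0.05), HOXA2 (0.26 ± 0.06) after SMARCB1 siRNA, and KDM6A after SMARCB1 (0.25 ± 0.06) and SMARCA4 siRNA (0.30 ± 0.06). These values were not recomputed under the alternatives.

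G1/S and G2/M genes were lower after SMARCA4 siRNA, which a dye effect does not explain, nor the control if it was 1 RNA in each line, since these cancel in the difference to SMARCA2 (median G1/S -0.42), nor does the slide (-0.46 within slide 3). It may rest mostly on siRNA 1: siRNA 1 minus siRNA 2 was -0.43 in 22Rv1 and -0.42 in LNCaP, although siRNA 2 lowered SMARCA4 as far. The test set beforehand for an off-target effect of 1 siRNA asked whether the G1/S median lay below both SMARCA2 arrays of the line, and it did on 4 of 4 SMARCA4 arrays, which by the bound written then would have excluded it. That bound was judged too weak after the values were seen, because siRNA 2 read -0.15 and -0.19 and SMARCB1 arrays reached -0.20, so an off-target effect of siRNA 1 and loss of SMARCA4 cannot be told apart. Chance cannot be excluded either, since 4 of 35 splits of the 8 SMARCA4 and SMARCA2 arrays gave a G1/S difference as large (real 0.42, highest other 0.43), and all 4 kept both SMARCA4 siRNA 1 arrays on 1 side.

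Effects that belong to the siRNA sequence may add to other results. Across genes, which are not independent replicates, the difference between siRNA 1 and siRNA 2 of a target correlated between lines at 0.15 to 0.20, against -0.04 to 0.06 for different targets in different lines. LMNB1 after SMARCA4 siRNA (-1.55 in 22Rv1, -1.5 in LNCaP) and MAPK6 after SMARCA2 siRNA (1.21 and 1.04), chosen after their values were seen, are examples.

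For the counts of genes that differed between targets, other splits of the 8 arrays decided nothing. With a line term limma called 0 for the real split, so 35 of 35 splits gave as many in each of the 3 differences (2662, 2341 and 2215 features at an unadjusted p under 0.05). The highest other counts, 350, 781 and 666, came from the split by cell line. That split was fitted without a line term, so its counts cannot be set against the 0 of the real split, and point only to the lines as a structure of the samples. The remaining splits gave 0.

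The changes against the non-targeting channel shared by all 3 targets may be partly technical. The control of each line, which the labels do not state to be 1 RNA, may add to them, since 47.5% of the covariance of different targets within a line was absent across lines. That share cannot single out the control. Anything else shared within a line, such as a slide or the LNCaP probe set described above, would raise it too. A gene-specific dye effect and a response common to all siRNAs cannot be told apart: over 5497 pairs of probes of 1 gene the mean of all arrays correlated at 0.27 (95% interval 0.24 to 0.29), between the bounds set for a dye effect and for a change of the gene, and dyes were not swapped. Differences between SMARCA4 arrays and the others correlated at 0.35, and over the 2988 pairs well above background in both channels on all arrays both values were higher, 0.34 for the mean and 0.55. A common response of the cells to any of the 3 knockdowns stays open, as untested.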
